A study of Mus musculus with 9 samples.

How the data were processed

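RNA from mouse gastrocnemius was made into libraries with Illumina's TruSeq RNA kit, version 2 (per the labels' protocols), which does not mark strand, and sequenced for 3 libraries of each of 3 genotypes at 3 months of age. The authors deposited whole-number counts of reads per gene symbol for 24062 symbols and 9 libraries, not normalized. The submitters' processing notes name TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6, Subread and the genome build mm10, with no role or order; the annotation, strand setting and filters are not given in the sources used here. Without strand, reads of a gene and of an overlapping gene on the other strand cannot be told apart. The list of 13 mitochondrially encoded genes was not analysed here. Of the symbols, 99.34% matched a single RefSeq gene of GRCm38.p6, a patch release of the assembly that mm10 names, used for coordinates, and 98.42% a GENCODE M21 transcript, used for length and GC content.

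Samples were grouped by the genotype in their titles. The labels do not say that libraries of a genotype came from separate animals, litters or days, so p-values measure the spread between these samples, which may be partly technical. No pair of libraries of a genotype agreed within sampling noise: chi-square per degree of freedom over genes ran from 14.3 to 65.6. Replicate numbers come from the titles, which do not say what they mark. Deviations from the genotype means correlated in all 3 same-numbered pairs of WT and hetL1002P libraries (r = 0.285, 0.36 and 0.516, against -0.454 to 0.198 for the other 6 pairs), which meets the bound of 0.1 set for pairing. Same-numbered pairs with hetX753 had r of -0.279 to 0.164 and did not meet it. Within a genotype the 3 deviations cancel, so these r are not independent of each other. Much of the agreement may rest on WT 3 and hetL1002P 3, so that pairing is not established. The fit of all libraries has no block, and fits with a block are alternatives. Library totals ran from 19768149 to 33977252, and a gene at Bub1b's level rests on 2 to 21 counts per library. In every library Xist had at most 1 count while Ddx3y had 378 to 1190, so all libraries had a male pattern.

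The tests used edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr on genotype (12989), TMM scaling, robust dispersion, and a quasi-likelihood fit of all 9 libraries with genotype as the only term (6 residual degrees of freedom). Each pair of genotypes was compared with glmQLFTest, and all 3 jointly with a test on 2 degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was called, with no minimum fold. Every adjusted p given for a gene without another tool's name comes from this test. A positive log2 fold change means higher in the genotype named first; its standard error was computed as its size divided by the square root of the F statistic. Levels are given in CPM, counts relative to the TMM-scaled library total, as mean ± SD of 3 libraries. With library totals alone as scaling, the median gene moved by 0.12 on the log2 scale in hetX753 against WT and by 0.10 in hetL1002P against WT, so fold changes are relative to the typical gene.

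Fixed before the data were examined were the groups, tests, gene lists, rule for named genes and most alternatives. The rule took, in each comparison, among genes past the threshold that averaged at least 1 CPM, the 12 highest and 12 lowest log2 fold changes, leaving out predicted genes named Gm with digits, names ending in Rik and sex-linked genes. Where fewer than 5 genes passed in a direction those were named, and where fewer than 5 passed in both together, the 10 with the smallest p were named as not past the threshold. Bub1b was named in every sample, and from each list up to 4 members with the smallest p. Genes named outside this rule are marked as chosen after their values were seen, and a few that the rule takes are not reported here.

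The 31 lists covered the spindle checkpoint, p53 targets, secreted senescence-associated factors, interferon response, slow and fast fibres, atrophy and denervation, satellite cells, oxidative phosphorylation, glycolysis, fatty acid use, mitochondrially encoded genes, the integrated stress and unfolded protein responses, heat shock, proteasome, cytosolic ribosome, extracellular matrix, circadian clock, immediate early genes, glucocorticoid response and sex-linked genes. The remaining lists were markers of adipocytes, endothelium, smooth muscle, fibroblasts, tendon, macrophages, lymphocytes, neutrophils and mast cells, erythroid cells and Schwann cells. Lists with at least 5 tested members (27) were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. Camera compares a list with all other genes; camera with an estimated correlation, and fry, which tests whether members move, on balance, the same way or change in either direction, were alternatives.

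The test was tried on counts simulated from these libraries' means and sizes, with genes varying independently and no trend or deviating library. Recovery in the real data may thus be lower. The test was given 200 changed genes, all averaging at least 1 CPM, at 1.5-, 2- or 4-fold. For hetX753 against WT it recovered 74.6% of 2-fold and 20.9% of 1.5-fold changes, with 9 false calls among 139; for hetL1002P against WT 70.1% and 13.4%, with 6 among 126; and for hetX753 against hetL1002P 70.1% and 17.9%, with 14 among 138. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors, library totals alone, no low-count filter, at least 1 CPM in 3 libraries, only the genotypes compared, no robust estimation, a replicate block, 1 surrogate variable (sva 3.50.0), a minimum log2 fold change of 1 and each library left out. Chosen after seeing the data were a per-library correction for transcript length and GC content, by loess with a span of 0.5 passed to edgeR as an offset, leaving out WT 3 and hetL1002P 3 together, and, after the calls had been seen, the replicate block on WT and hetL1002P alone, with and without that correction, which leaves 2 residual degrees of freedom. Overlap between both carrier comparisons was set against 50 simulations of unchanged groups in which genes vary independently. Permutation tests drew 100000 times. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.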

Results

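Transcript levels were measured by RNA sequencing in gastrocnemius, a mixed-fibre calf muscle, of mice aged 3 months on a mixed 129Sve/C57BL/6 background. The 9 libraries came from 3 genotypes, with 3 libraries each: wild type (WT), and carriers of a single altered copy of Bub1b labelled hetL1002P and hetX753. Bub1b encodes BubR1, a kinase-like protein of the spindle assembly checkpoint, which holds cells before anaphase until chromosomes are attached. The series concerns alleles of this gene linked to mosaic variegated aneuploidy, and the design asks whether either allele alters muscle expression and whether the alleles differ. Totals of counted reads ran from 19768149 to 33977252 per library in WT, from 22795669 to 25712368 in hetL1002P and from 20106833 to 27797765 in hetX753. Of 24062 gene symbols, 12989 had enough counts to be tested. Log-CPM values correlated with r of 0.971 to 0.989 over the 9 pairs of libraries within a genotype and 0.962 to 0.989 over the 27 pairs between genotypes. On the first principal component (39.7% of the variance), WT 3 lay at -47.5 and hetL1002P 3 at -32.5, against -9.52 to 28.8 for the other libraries.

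Bub1b itself was scarcely transcribed in muscle. It was lower in both carriers than in WT, with a level of 0.654 ± 0.107 CPM in WT, 0.271 ± 0.156 CPM in hetL1002P and 0.278 ± 0.0432 CPM in hetX753 (SD, n = 3 each). The gene lies on chromosome 2 from 118598202 to 118641592 (GRCm38). The libraries held 21, 11 and 16 Bub1b counts in WT, 10, 9 and 2 in hetL1002P and 8, 8 and 5 in hetX753. The log2 fold change was -1.21 (SE 0.44) in hetX753, 2.31-fold lower than WT, with adjusted p = 0.177. In hetL1002P it was -1.21 (SE 0.44), 2.32-fold lower, with adjusted p = 0.579, so neither passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg). For this gene, fixed beforehand, the unadjusted p of the same test in hetX753 was 0.0189. Fold change and SE were alike in both carriers, so the gap between the adjusted p of 0.177 and 0.579 reflects the other genes of each comparison. All 6 carrier libraries lay below all 3 WT libraries. Between the carriers the log2 fold change was 0.01 (SE 0.50).

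In hetX753 muscle, Cpt1a and Ucp3 were higher than in WT. Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose 2.77-fold, from 4.26 ± 0.301 to 11.8 ± 2.98 CPM, and Ucp3, a muscle uncoupling protein of the inner mitochondrial membrane, rose 3.00-fold, from 48.6 ± 2.77 to 146 ± 47.4 CPM (SD, n = 3). The potassium channel subunit Kcnab1 rose 3.76-fold and the glutamate transporter Slc1a3 3.51-fold. Genes that fell included Tbc1d4, a Rab GTPase-activating protein of insulin-stimulated glucose uptake, which dropped from 34.1 ± 10.5 to 10.6 ± 1.21 CPM, and Pla2g7, a hydrolase of platelet-activating factor, which dropped from 61.6 ± 11.9 to 18.3 ± 4.02 CPM. The call of Ucp3 was lost with no low-count filter (adjusted p = 0.0632), at least 1 CPM in 3 libraries (0.0515), the replicate block (0.0505), 1 surrogate variable (0.0832) and without both WT 3 and hetL1002P 3 (0.0543), that of Pla2g7 with 1 surrogate variable (0.0569) and without both libraries (0.0607), and that of Slc1a3 with library totals alone (0.0612). Of the 9 fits without 1 library, Cpt1a, Ucp3 and Slc1a3 kept their calls in 3, Pla2g7 in 5, and Kcnab1 and Tbc1d4 in 6. In all, 66 of 12989 genes passed an adjusted p of 0.05, 43 higher and 23 lower, and 38 of them differed by at least 2-fold.

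**Figure D1:**
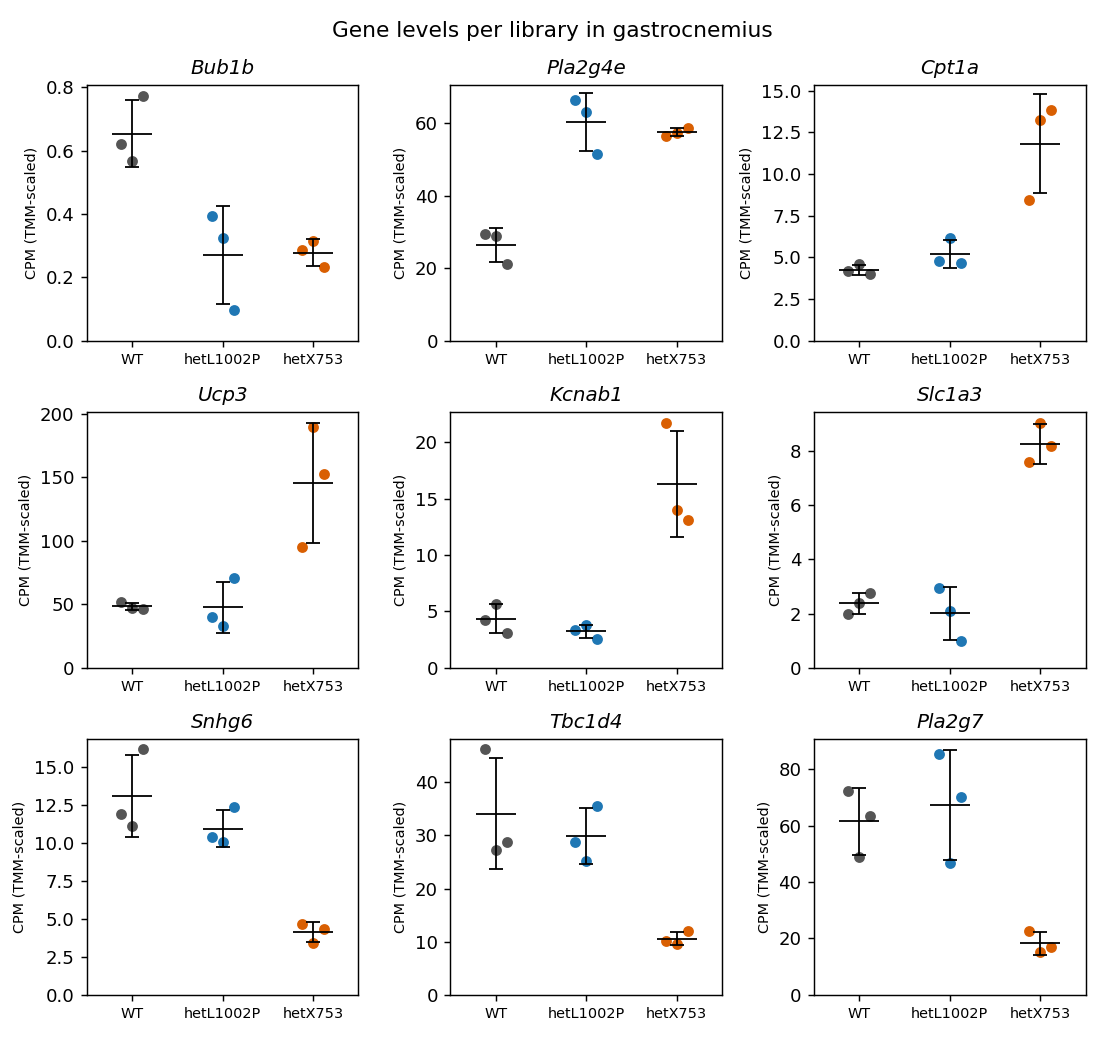
Levels of 9 genes in CPM (y axis, TMM-scaled, from 0) in each library of the 3 genotypes (x axis); points are libraries, and the bar and whiskers are the mean and SD of 3 libraries. Cpt1a, Ucp3, Kcnab1 and Slc1a3 lie higher and Snhg6, Tbc1d4 and Pla2g7 lower in hetX753, while Pla2g4e averages 57.5 CPM in hetX753 and 60.3 CPM in hetL1002P against 26.4 CPM in WT.

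The steepest rises in hetX753 among genes averaging at least 1 CPM were in Eno1b, a retrotransposed enolase copy, at 18.1-fold (log2 4.18, SE 0.74, adjusted p = 0.0395). Its call was lost with limma-voom (adjusted p = 0.136), with library totals alone (0.063), with no low-count filter (0.108), on the 2 genotypes alone (0.086), with 1 surrogate variable (0.152), with length and GC content corrected (0.0614) and without both WT 3 and hetL1002P 3 (0.168), and it was kept in 1 of 9 fits without 1 library, that without hetX753 2. Its level varied between libraries, at 13.7 ± 10.2 CPM, and its reads cannot be separated with certainty from those of its parent gene. Grk1, the rhodopsin kinase, was 5.53-fold higher, the sodium-proton exchanger Slc9a7 5.43-fold and Pyroxd2 5.13-fold. Akr1c14, an aldo-keto reductase, was 3.43-fold higher, Ankrd33b 2.70-fold, Sec31b 2.64-fold and Ocel1 2.52-fold. The adjusted p of these genes ran from 0.0168 for Slc9a7 and Ankrd33b to 0.0439 for Akr1c14. Among the deepest falls were those in the pseudogene Gpr137b-ps (log2 -2.67), the small nucleolar RNA host gene Snhg18 (log2 -2.52), Lrtm2 (log2 -2.20) and Cyp2f2 (log2 -1.86, adjusted p = 0.0309). Snhg6, another small nucleolar RNA host gene on chromosome 1 from 9942025 to 9944118, was 3.17-fold lower, Fut10 3.09-fold, the phosphatase gene Dusp26 2.99-fold, Sbk2 2.56-fold and Parp3, an ADP-ribosyltransferase gene, 2.17-fold. With library totals alone, Pyroxd2, Akr1c14, Sec31b, Lrtm2, Cyp2f2, Fut10, Dusp26 and Parp3 lost their calls (adjusted p from 0.0503 to 0.0732). Fut10 also did with 1 surrogate variable (0.0528) and without both WT 3 and hetL1002P 3 (0.0536), and Dusp26 with these (0.141 and 0.102), the length and GC correction (0.0535) and the block (0.0565). In the 9 fits without 1 library the genes of this paragraph kept their calls in 1 (Eno1b and Akr1c14) to 7 (Ankrd33b and Snhg6). Exons of Snhg6, Pla2g7, Parp3, Kcnab1, Ocel1, Cyp2f2 and Pyroxd2 overlap a gene on the other strand, and those of Sec31b and Akr1c14 one on the same strand, so that their counts may include reads of that gene.

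Other genes that passed in hetX753 were the growth factor Igf2 (log2 0.85, adjusted p = 0.0195), catalase (Cat, log2 0.66, adjusted p = 0.0487), the cation channel Trpm7 (log2 1.07, adjusted p = 0.0388) and the signalling inhibitor Spry1 (log2 -0.86, adjusted p = 0.045). Igf2, Cat and Trpm7 were chosen for mention after their values were seen. With library totals alone Cat (0.0927), Trpm7 (0.0869) and Spry1 (0.143) lost their calls by adjusted p, with at least 1 CPM in 3 libraries Cat (0.0529) and Spry1 (0.0515), with the block Cat (0.0565) and with the length and GC correction Spry1 (0.0624). Exons of Pla2g4e and Igf2 overlap another gene on the same strand, and those of Spry1 one on the other strand. Pla2g4e, a phospholipase A2 gene on chromosome 2 from 120166412 to 120245630, rose 2.18-fold (log2 1.12, SE 0.15, adjusted p = 0.0195), from 26.4 ± 4.68 to 57.5 ± 1.13 CPM. The predicted gene Gm14085 on the same chromosome had 0, 1 and 0 counts in WT and averaged 0.945 ± 0.247 CPM in hetX753 (adjusted p = 0.0168). All 66 genes kept their direction in the 9 fits that left out 1 library, but 0 of the 66 passed in all 9 of them. The count fell to 0 without WT 1, 9 without WT 2, 7 without WT 3, 13 without hetL1002P 1, 34 without hetX753 1, 17 without hetX753 2 and 3 without hetX753 3, and rose to 669 without hetL1002P 3. DESeq2 called 660 genes, limma-voom 537, edgeR with library totals as the only scaling 31, edgeR on the 2 genotypes alone 254, edgeR with 1 surrogate variable 233, and edgeR without both WT 3 and hetL1002P 3 340.

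Among the gene lists, 5 of 27 lay lower in hetX753 than in WT and 0 higher by camera. Nuclear genes of oxidative phosphorylation had 45 of 46 members below 0, with a median log2 fold change of -0.35 (adjusted p = 4.43e-06), and Cox6a2 stood at -0.54 and Cox5a at -0.72. Cytosolic ribosomal protein genes had 47 of 48 below 0, median -0.32 (adjusted p = 3.15e-07), with Rps16 at -0.46, and proteasome subunits 29 of 31, median -0.26 (adjusted p = 0.00034), with Psmb5 at -0.63. Fibroblast and fibro-adipogenic progenitor markers had 16 of 18 below 0, median -0.35 (adjusted p = 0.00194), and macrophage markers 15 of 18, median -0.35 (adjusted p = 0.0262), with Pcolce at -0.57 and Aif1 at -1.41. All 5 calls were lost with the correlation between members estimated from the data: adjusted p = 0.921 for each with an estimated correlation. By the gene test, 0 members of these 5 lists passed over all genes (edgeR; DESeq2 called 660 genes and limma-voom 537 in this comparison, and 2718 genes had an unadjusted p under 0.05), and Pcolce was the 1 member that passed adjusted over the list alone. Without WT 3, which lay apart on the first component, 8 lists were called but not the proteasome (adjusted p = 0.131); without WT 2 the macrophage list was not (adjusted p = 0.188), and without hetX753 1 the lists called numbered 9. Without both WT 3 and hetL1002P 3 they numbered 7, with adjusted p = 0.0549 for proteasome and for macrophage genes, and with the trend on transcript length and GC content removed only the fibroblast list of these 5 was called (adjusted p = 0.00646), against 0.18 for oxidative phosphorylation, 0.148 for proteasome, 0.478 for ribosomal and 0.297 for macrophage genes.

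Of the 34 measured genes of fatty acid use, 2 rose over all genes tested (Cpt1a and Ucp3) and 0 fell. Adjusted over the list alone, 3 rose: those and the acyl-CoA thioesterase Acot2, at log2 1.11 (list-alone adjusted p = 0.0209). As a list, these genes had a median of 0.05 and a mean of 0.29 and did not pass (camera adjusted p = 0.169). The satellite cell and myogenesis list had 1 member lower over all genes, Spry1, and adjusted over the list alone 1 higher, the dystrophin gene Dmd (log2 1.11), and 2 lower, Spry1 and Sdc4 (log2 -0.50). Its median was 0.08 while its test pointed lower (camera adjusted p = 0.907). In the spindle checkpoint list, 10 of 28 genes in the table were expressed enough to test, and none passed, also adjusted over the list alone. Its median was 0.03, its mean -0.19 and its test pointed lower (camera adjusted p = 0.998), with Cdc27 at 0.50 and Pttg1 at -2.02. Targets of p53 and cell cycle inhibitors had 11 of 25 members above 0 and a median of -0.04 (camera adjusted p = 0.533), with Cdkn1c at 0.48 and Cdkn2c at -0.51.

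**Figure D2:**
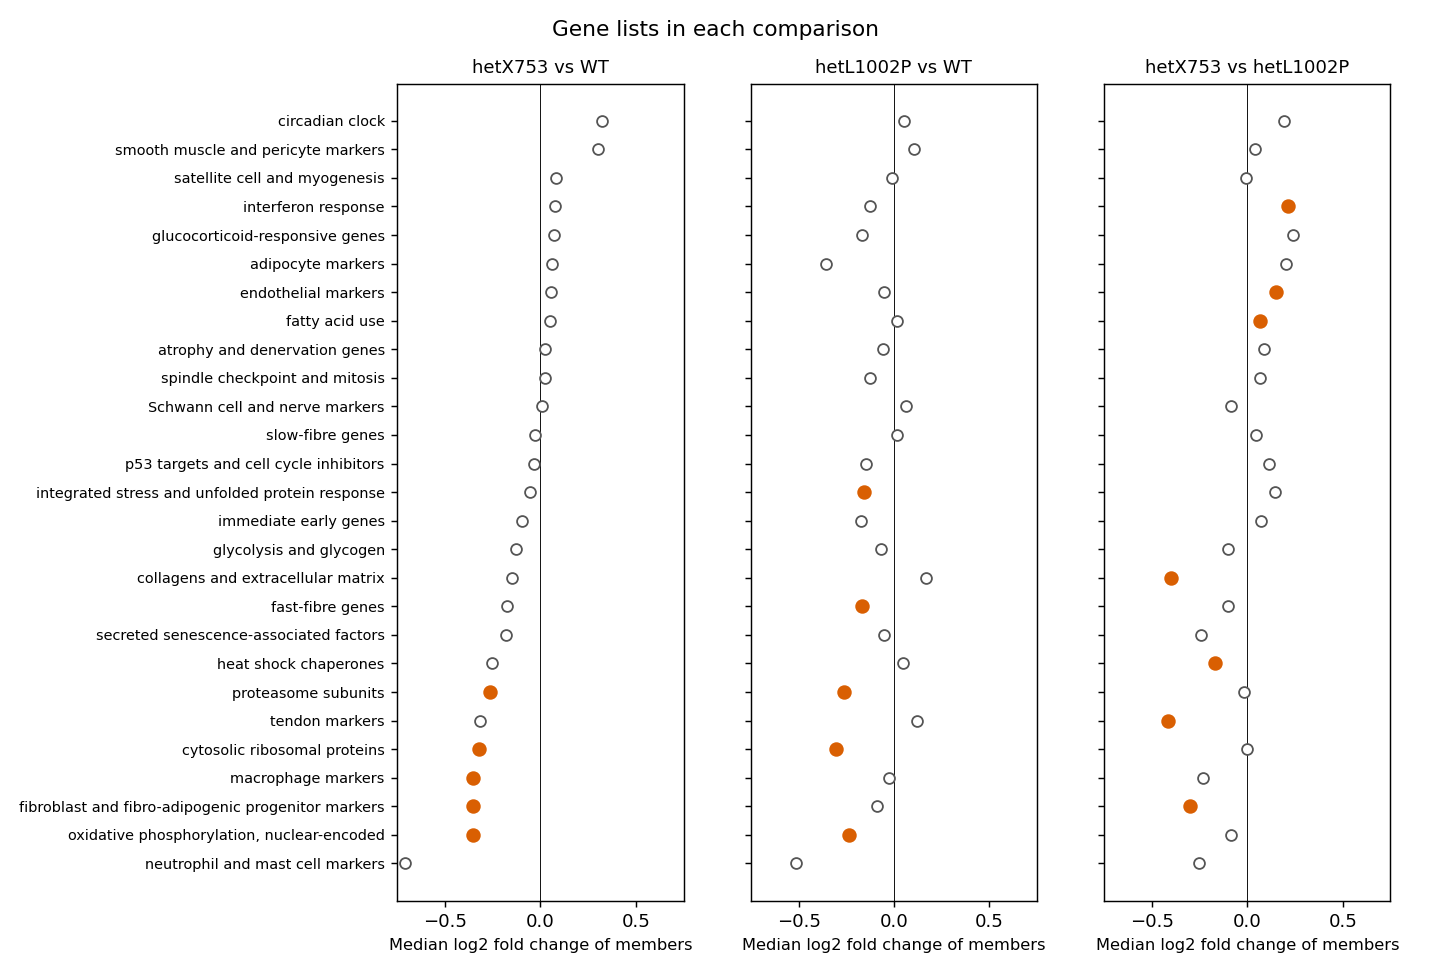
Median log2 fold change of the members of each of 27 gene lists (x axis) in the 3 comparisons (panels); filled points are lists called by camera with its preset correlation, open points lists that were not. With an estimated correlation 0 lists are called in any comparison. No median of a called list changes sign with another scaling, although the medians shift in size with library totals alone.

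In hetL1002P muscle, whether single genes passed against WT depended on the fit. The edgeR fit of all 9 libraries called 0 of 12989 genes, with 1034 genes at an unadjusted p under 0.05, where DESeq2 called 5 and limma-voom 1. With the replicate number as a block, on WT and hetL1002P alone, edgeR called 635 genes, 334 higher and 301 lower, but 30, 4 and 227 without the pair numbered 1, 2 and 3, and with the length and GC trend also removed 1, Pla2g4e (adjusted p = 0.00462). The genes with the smallest p were led by Pla2g4e, at 60.3 ± 7.89 against 26.4 ± 4.68 CPM (SD, n = 3), 2.28-fold (log2 1.19, SE 0.15, adjusted p = 0.0802). It passed with DESeq2 (adjusted p = 9.6e-10), limma-voom (0.00101), no low-count filter (0.019), 1 surrogate variable (0.000885), the length and GC correction (0.00606), the block on WT and hetL1002P alone (0.000218), and without both WT 3 and hetL1002P 3 (0.00195). It did not pass with the block in all 9 libraries (0.0686), DESeq2 size factors (0.0743), no robust estimation (0.0793), at least 1 CPM in 3 libraries (0.114) or library totals alone (0.369), and reached 0.445 on the 2 genotypes without the block. The potassium channel gene Kcnma1 stood at log2 0.61, Tm6sf1 at 0.84, the microtubule-associated Map1a at 0.66, Tmem56 at 0.49, Vps13c at 1.23, the neuromuscular junction kinase gene Musk at 0.99 and Fam120c at 0.52. Dynlt1b stood at -1.38 and the glutathione transferase gene Gstm2 at -0.47, all with adjusted p = 0.579. With the block on WT and hetL1002P alone, the 9 genes after Pla2g4e had an adjusted p from 0.000733 for Vps13c to 0.0421 for Tm6sf1. With the trend also removed it ran from 0.0577 for Vps13c, Musk and Dynlt1b to 0.422 for Gstm2. Exons of Map1a, Kcnma1, Tm6sf1 and Fam120c overlap a gene on the other strand. Gm14085, named after its values were seen, averaged 0.799 ± 0.149 CPM (adjusted p = 0.0802, and 0.0157 with the block on WT and hetL1002P alone). Simulated 2-fold changes in this comparison were recovered for 47 of 67 genes, and 1.5-fold changes for 9 of 67. These were genes averaging at least 1 CPM in counts without a trend between libraries, so the shares may not carry over to the real data. Genes called in hetL1002P against WT numbered 1 without hetL1002P 3 and 0 with each other library left out.

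**Figure D3:**
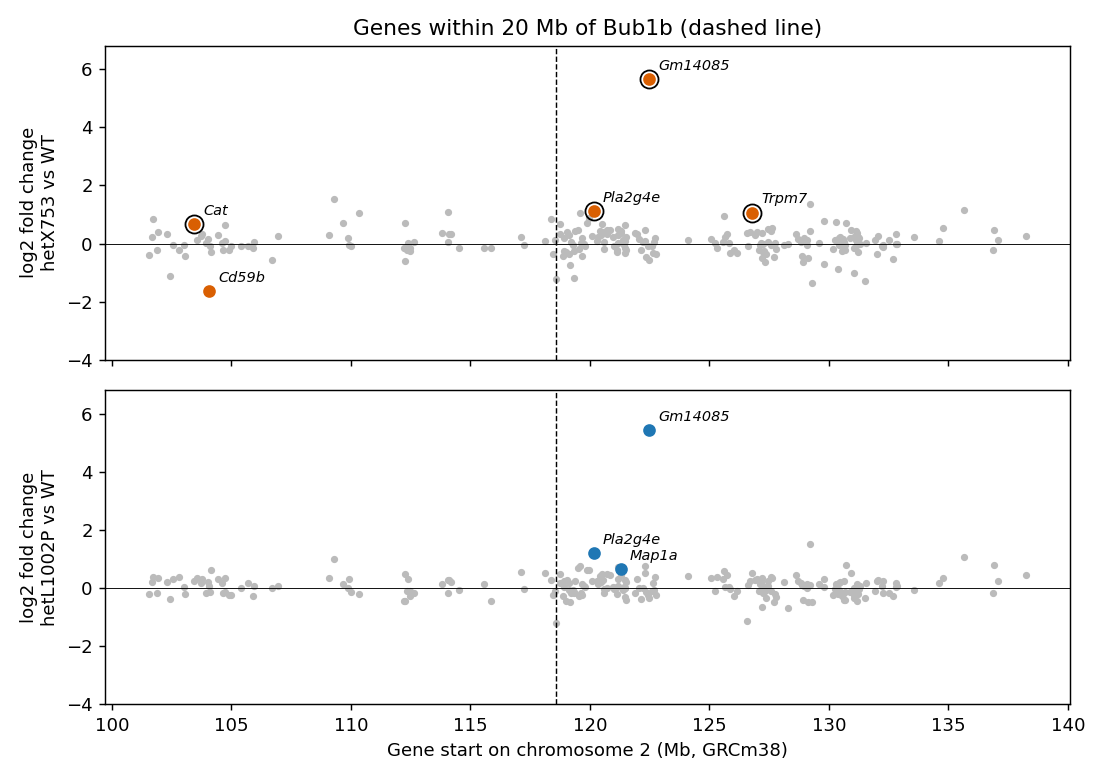
Log2 fold change against WT (y axis) of tested genes whose start lies within 20 Mb of Bub1b on chromosome 2 (x axis, Mb; dashed line, Bub1b) in hetX753 (top) and hetL1002P (bottom). Coloured points have an unadjusted p under 0.001 and ringed points an adjusted p under 0.05; the value of Gm14085, which had 1 count in WT, depends on the prior count.

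By camera, 5 of 27 lists lay lower in hetL1002P than in WT and 0 higher. All 48 cytosolic ribosomal protein genes were below 0, with a median log2 fold change of -0.30 (adjusted p = 1.31e-13), and Rpl18 stood at -0.46. All 31 proteasome subunits were below 0, median -0.26 (adjusted p = 7.38e-07), with Psmb5 at -0.43, and 43 of 46 oxidative phosphorylation genes, median -0.23 (adjusted p = 4.7e-06), with Cox6a2 at -0.46. The list of the integrated stress and unfolded protein responses had 23 of 28 members below 0, median -0.15 (adjusted p = 0.0232), with Atf4 at -0.41, and fast-fibre genes 14 of 19, median -0.17 (adjusted p = 0.0292), with Tnnc2 at -0.47 and Myh1 at 0.46. Each had adjusted p = 0.979 with an estimated correlation. No member passed over all genes, and adjusted over the list alone Musk was the 1 that passed, in the list of atrophy and denervation genes. The spindle checkpoint list had a median of -0.12 (adjusted p = 0.809) and the p53 list one of -0.15 (adjusted p = 0.108). With the block on WT and hetL1002P alone, 7 lists were called, the p53 list (adjusted p = 0.0465) and immediate early genes (adjusted p = 0.0344) in addition, each of the 7 at adjusted p = 0.933 with an estimated correlation, and with the trend also removed the proteasome and ribosomal lists alone. Oxidative phosphorylation was no longer called without WT 3 (adjusted p = 0.0838), the stress list without WT 2 (0.0959) or hetL1002P 2 (0.075), and fast-fibre genes without WT 3 (0.06), hetL1002P 1 (0.068) or hetL1002P 2 (0.192). The list count was 8 without WT 1, 11 without hetL1002P 2 and 8 without both WT 3 and hetL1002P 3. With the length and GC trend removed it was 2, the proteasome (adjusted p = 0.00196) and ribosomal lists (adjusted p = 0.00172).

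The alleles differed directly in a small set of genes. Iigp1, an interferon-inducible GTPase gene, was 8.28-fold higher in hetX753 than in hetL1002P, at 32.2 ± 8.37 against 3.9 ± 0.579 CPM (SD, n = 3). It was called against WT in neither carrier in the fit of all libraries, so these calls do not tell a rise in hetX753 from a fall in hetL1002P. Kcnab1 was 5.05-fold higher in hetX753 than in hetL1002P, at 16.3 ± 4.73 against 3.21 ± 0.611 CPM. Slc1a3 was 4.06-fold higher, Ocel1 2.95-fold, Ankrd33b 2.26-fold and Trappc12, a vesicle-tethering subunit gene, 1.78-fold. Lower in hetX753 were Gpr137b-ps (log2 -2.88), Pla2g7 (log2 -1.88), Tbc1d4 (log2 -1.49), Snhg6 (log2 -1.41), Limd1 (log2 -1.15), Parp3 (log2 -1.10) and Ccdc43 (log2 -0.69). In all, 15 of 12989 genes passed, 8 higher and 7 lower, with adjusted p of the genes named here from 0.023 for Kcnab1 to 0.0422 for Ccdc43. On these 2 genotypes alone Slc1a3, Ocel1, Ankrd33b, Trappc12, Gpr137b-ps, Pla2g7, Snhg6, Parp3 and Ccdc43 lost their calls (adjusted p from 0.059 to 0.102), with library totals alone Slc1a3, Ankrd33b, Trappc12, Tbc1d4, Limd1, Parp3 and Ccdc43 (0.0689 to 0.0841), without both WT 3 and hetL1002P 3 Ankrd33b (0.0685), Pla2g7 (0.0987) and Limd1 (0.0569), and with no low-count filter Iigp1 (0.0769). Cpt1a was 2.27-fold higher (adjusted p = 0.0632) and Ucp3 3.06-fold higher (adjusted p = 0.0707), which did not pass over all genes. Adjusted over the list alone, Cpt1a, Ucp3 and Angptl4 were the 3 of 34 genes of fatty acid use that rose. All 15 genes kept their direction, and 0 of them passed, in all 9 fits without 1 library. Among the genes named here, Ccdc43 kept its call in 0 of these fits, Slc1a3 and Ankrd33b in 1, Iigp1 and Limd1 in 3, Pla2g7 in 6 and Kcnab1 in 7, with the others in between. Genes called numbered 0 without hetL1002P 1, 2 without hetL1002P 2, 7 without hetX753 1 and 3 without hetX753 3. DESeq2 called 138 genes, limma-voom 342, and edgeR on these 2 genotypes alone 5.

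Of the lists, 3 lay higher in hetX753 than in hetL1002P: interferon response genes (23 of 28 members above 0, median 0.21, adjusted p = 0.0199, with Tap1 at 0.75 and Rsad2 at -1.10), fatty acid use (23 of 34, median 0.07, adjusted p = 0.0433) and endothelial markers (16 of 20, median 0.15, adjusted p = 0.0495, with Egfl7 at 0.29). Iigp1 is not in the interferon list. A further 4 lay lower: collagens and extracellular matrix (34 of 38 below 0, median -0.40, adjusted p = 0.00119), with Col1a1 at -0.73; heat shock chaperones (18 of 20, median -0.17, adjusted p = 0.00254), with Hsph1 at -0.63; fibroblast markers (16 of 18, median -0.30, adjusted p = 0.0199); and tendon markers (10 of 12, median -0.41, adjusted p = 0.0301), with Thbs4 at -0.47. Each had adjusted p = 0.877 with an estimated correlation. The spindle checkpoint list (median 0.07, adjusted p = 0.851) and the p53 list (median 0.11, adjusted p = 0.495) did not pass. Only 4 lists were called without hetL1002P 1, hetL1002P 2, hetX753 1, hetX753 2 or hetX753 3, and each of the 7 lost its call without some library. By adjusted p, the collagen list did so without hetL1002P 1 (0.0535) or hetL1002P 2 (0.195), the fibroblast list without hetL1002P 1 (0.0535), hetL1002P 2 (0.491) or hetX753 1 (0.0552), the heat shock list without hetL1002P 3 (0.113), and the tendon list without hetL1002P 1 (0.261), hetL1002P 2 (0.239), hetX753 1 (0.319) or hetX753 2 (0.0985). The interferon list did so without hetL1002P 1 (0.0778), hetL1002P 3 (0.0763), hetX753 1 (0.122) or hetX753 3 (0.395), fatty acid use without hetL1002P 1 (0.101), hetL1002P 2 (0.466), hetX753 2 (0.211) or hetX753 3 (0.0739), and the endothelial list without WT 1 (0.0514), hetL1002P 3 (0.479), hetX753 1 (0.121), hetX753 2 (0.0985) or hetX753 3 (0.0523). Without both WT 3 and hetL1002P 3, the interferon (adjusted p = 0.128), heat shock (adjusted p = 0.166) and endothelial lists (adjusted p = 0.558) were no longer called.

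Across all 3 genotypes, 28 genes differed by the joint test, a count that ran from 0 without hetL1002P 1 to 209 without hetL1002P 3. It was 3 without WT 1, 11 without WT 2, WT 3 or hetX753 2, and 6 without hetX753 3; DESeq2 called 384. The effects of both alleles against WT correlated across genes, which are not independent replicates, with r = 0.62. Unchanged groups simulated against shared WT libraries gave a mean r of 0.50 (0.48 to 0.53 over 50 simulations). The covariance was 0.0941 against 0.0391 simulated (0.0361 to 0.0416), a difference of 0.0549, and 76.4% of genes had the same sign against 66.8%. With the length and GC trend removed the observed r was 0.53, the covariance 0.0617 and the share 70.0%, smaller than without the correction. They lay above the highest simulated values of 0.527, 0.0416 and 68%, for r only barely. These were simulated without such a trend and not corrected. Genes vary independently in the simulations, so the simulated ranges may be too narrow, and the excess does not show a shared effect of the alleles. Of the 66 genes called in hetX753, 57 had the same sign in hetL1002P and 22 of those 66 an unadjusted p under 0.05 there. The 66 genes with the smallest p in the simulated unchanged groups gave means of 61.7 (58 to 65) and 26.7 (18 to 36). This agreement thus does not exceed that of simulated shared controls, which hold no deviations shared by same-numbered libraries. In this fit no gene was called in both, and the overlap of independent lists is also 0 because it called 0 genes in hetL1002P. Pla2g4e was called in both with DESeq2, limma-voom, no low-count filter, 1 surrogate variable, the length and GC correction, and without both WT 3 and hetL1002P 3. The 3 WT libraries cannot be split into groups of 2, so part of the excess may come from the shared controls.

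**Figure D4:**
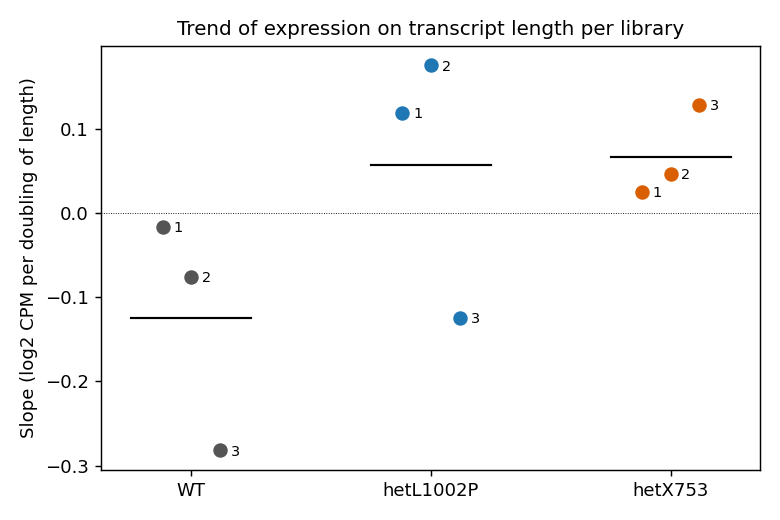
Slope of log2 CPM on the log2 of transcript length in each library, relative to the mean of all libraries (y axis, per doubling of length), by genotype (x axis); points are libraries with their numbers and lines are the mean of 3. WT 3 lies at -0.28 and hetL1002P 3 at -0.12, and the genotype means are -0.12 in WT, 0.06 in hetL1002P and 0.07 in hetX753.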

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

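The tests of strain-derived blocks, of genes near Bub1b and of paired splits were chosen after the result was seen, as was the correction for length and GC content; the others here were planned or had their prediction written first. In the direct contrast, the effect against WT of 15 genes differed between hetX753 and hetL1002P, among them Kcnab1 (log2 2.34), Iigp1 (log2 3.05) and Tbc1d4 (log2 -1.49). For hetX753 against WT, the real grouping called 66 genes and the highest of the other splits of the 6 libraries called 1; for hetX753 against hetL1002P these were 15 and 1. For hetL1002P against WT the real grouping called 0 genes, so that all 10 splits called as many, and the highest other split called 674. That split set WT 1, hetL1002P 1 and hetL1002P 2 against WT 2, WT 3 and hetL1002P 3, which points to a structure of these samples. It keeps the pairs numbered 1 and 3 together; of the 4 splits that part all 3 pairs of WT and hetL1002P, each called 0, and with the pair as a block the real one called 635 and the highest other 0, too few splits for a share under 0.05. With 10 splits, a share under 0.05 cannot be reached, and in the first 2 comparisons 1 of the 10, the real one, gave as many. In the joint test of 3 genotypes, 3 of 100 drawn splits, the real one among them, gave 28 genes or more. This share is under 0.05, the bound set beforehand, but was not adjusted over the comparisons. Other splits called 107 and 328, which again points to a structure of the samples, so chance is argued against there but not excluded. Of the 45 drawn splits that part all 3 pairs of WT and hetL1002P only the real one gave as many. Among these the highest other called 1, while the split with 328 parts 1 pair.

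Some genes near Bub1b had higher values in both carriers. The random draws used here treat genes as independent, so neighbours that vary together count more than once and the permutation p may be too small. In hetL1002P against WT, 3 of the 5 genes with an unadjusted p under 0.001 (Pla2g4e, Map1a and Gm14085) lay within 20 Mb of Bub1b, where 1.82% of tested genes lie (permutation p = 5e-05, one-sided; adjusted 0.0005 over 10 such tests), and in hetX753 4 of the 66 called genes did (Cat, Pla2g4e, Gm14085 and Trpm7; permutation p = 0.032, adjusted 0.107), but 5 of 161 with an unadjusted p under 0.001 (permutation p = 0.17); with the pairs of WT and hetL1002P as a block, 13 of 319 genes under 0.001 lay there in hetL1002P (permutation p = 0.0056, not adjusted), and with the length and GC correction as well 4 of 95 (permutation p = 0.093). The 5 genes in hetL1002P are fewer than chance alone would put under 0.001 among 12989 tested genes, and Map1a lay just inside (unadjusted p = 0.000966, edgeR). The permutation p of 5e-05 thus rests on a small set that depends on the cutoff. A trend on length and GC content is argued against for Pla2g4e, the gene named in its prediction, in both carriers. With the correction Pla2g4e had an adjusted p of 0.00478 in hetX753 and 0.00606 in hetL1002P at log2 1.05 and 1.11 (over all alternatives 2.96e-09 to 0.0914 in hetX753 and 9.6e-10 to 0.445 in hetL1002P). It is also argued against for Cat and Gm14085 in hetX753, which stayed called (adjusted p = 0.0385 and 0.0138). Trpm7 stayed called too (adjusted p = 0.0194) but went from log2 1.07 to 0.75, by more than its SE of 0.19, so part of its rise may follow the trend. In hetL1002P Gm14085 went from 5.42 to 5.37 (adjusted p = 0.0921) and Map1a from 0.66 to 0.40 (adjusted p = 0.832). A candidate explanation is sequence carried along with each targeted allele from the strain in which it was made, or an effect of the alleles on their neighbours, and the test cannot part these. Both stay open as hypotheses, since no strain variants were read here.

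Genes called in hetX753 against WT lay close together on chromosomes. Of 66, 26 had another called gene within 2 Mb, in 12 blocks on 10 chromosomes, against a mean of 11.1 in random draws (permutation p = 0.00066, one-sided); they include Trappc12 with Tssc1, Dusp26 with Fut10, Ankrd33b with Snhg18, Pla2g7 with Clic5, and Mau2 with Sugp2 and Ocel1. The length and GC trend is argued against, since 25 of the 26 kept their direction and an adjusted p under 0.1, the bound set beforehand, with the correction, and 21 an adjusted p under 0.05. On this mixed background, blocks of strain-derived chromosome shared by the hetX753 animals may account for it, and 6 of the 12 blocks held genes of both directions, while at an unadjusted p under 0.05 all 26 genes differed from hetL1002P in this direction and 8 differed between hetL1002P and WT in it, neither of which decides, since these comparisons share libraries with the one that picked the genes. Neighbours that vary together in any grouping stay open, because the top 66 genes of the other splits held up to 23 clustered genes (median 14, SD 4.56), and so does an effect of the allele.

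Long transcripts were higher on average in both carriers than in WT, although the slope of hetL1002P 3 (-0.12) lay below those of WT 1 (-0.02) and WT 2 (-0.08), and within same-numbered pairs hetL1002P lay above WT in 3 of 3, by 0.14, 0.25 and 0.16 (3 pairs allow no exact p below 0.25): across 12917 genes, which are not independent replicates, the log2 fold change correlated with transcript length with a Spearman rho of 0.47 in hetX753 and 0.59 in hetL1002P. A technical trend between libraries could give this but stays open, since the slopes on length of the WT libraries alone spanned 0.27, 1.43 times the difference of 0.19 between carriers and WT, but 0.06, 0.55 times a difference of 0.11, without WT 3 (-0.28), and 0.86 times without WT 1; the hetL1002P libraries spanned 0.30, and 0.06 without hetL1002P 3. A difference in library size also stays open: over 9 libraries the slopes had a Spearman rho of 0.233 with the totals (exact permutation p = 0.552) and a Pearson r of 0.097 (exact permutation p = 0.796), 0.143 and 0.131 without the 2 farthest totals. The rho met the bound of 0.3 set beforehand for excluding library size, but ran from 0.02 to 0.50 with 1 library left out; taking the values without 1 library into account, for both explanations, was decided after they were seen. An effect of the alleles was not tested apart from the trend, and in hetX753 the oxidative phosphorylation, ribosomal and proteasome lists lost their calls with the length and GC correction (adjusted p = 0.18, 0.478 and 0.148), while in hetL1002P oxidative phosphorylation did (0.491) and the ribosomal (0.00172) and proteasome lists (0.00196) did not; with an estimated correlation none of these was called even without it (adjusted p = 0.921 in hetX753 and 0.979 in hetL1002P).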

How the results depend on the processing

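The correction for length and GC content, the fit without both WT 3 and hetL1002P 3 and the block on WT and hetL1002P alone were chosen after the data were seen. Genes called in hetX753 against WT numbered 66, and 660 with DESeq2, 537 with limma-voom, 31 with library totals alone, 254 with only the 2 genotypes compared, 233 with 1 surrogate variable, 340 without both libraries, 38 with a log2 fold change of at least 1, and 0 to 669 with 1 library left out. For hetL1002P against WT they numbered 0 (1034 at an unadjusted p under 0.05), and 5 with DESeq2, 1 with limma-voom, 2 with no low-count filter, 1 with 1 surrogate variable, 1 with the length and GC correction, 2 without both libraries, 635 with the block on these 2 genotypes alone, 1 with that block and the correction, and 0 to 1 with 1 left out. For hetX753 against hetL1002P they numbered 15, and 138 with DESeq2, 342 with limma-voom, 38 with no filter, 5 with only the 2 genotypes, 158 with 1 surrogate variable, 41 with the length and GC correction, 95 without both libraries and 0 to 19 with 1 left out. For the joint test they numbered 28, and 384, 311, 16 with library totals alone, 58 with no filter, 154, 57 and 194 in the same order, and 0 to 209 with 1 left out. Lists called fell from 5, 5 and 7 to 0 in each comparison with an estimated correlation and with fry's test of movement in one direction; they numbered 3 in hetX753 and 2 in hetL1002P against WT with the length and GC correction (2 also with the block on 2 genotypes), 8 in hetL1002P without both libraries, and 5 to 9, 5 to 11 and 4 to 10 with 1 left out. Between the alleles the log2 fold change of Bub1b, 0.01 with all libraries, was -0.33 with limma-voom, -0.0014 with 1 surrogate variable, -0.35 without both libraries and -0.35 to 0.35 with 1 left out; against WT it stayed below 0 in every fit that gave it an adjusted p. The correlation of both allele effects went from 0.62 to 0.53 with the length and GC correction. The cause was not tested for any of these. Fewer genotypes or libraries leave fewer residual degrees of freedom, which alone would lower the counts. It does not account for the rise in hetX753 against WT to 254, 340 and 669 genes, the last without hetL1002P 3. Of 73 called values of named genes, all 69 to which DESeq2 gave an adjusted p stayed called with it, 72 with limma-voom, 64 with the length and GC correction, 64 without both libraries, 36 with library totals alone and 62 with the block in all libraries, but with 1 library left out 4 (hetX753 3), 11 (WT 1), 12 (hetL1002P 1), 15 (WT 3), 18 (hetX753 2), 19 (WT 2), 27 (hetX753 1), 53 (hetL1002P 2) and 68 (hetL1002P 3), and 0 reversed in any fit. With the replicate number as a block in all 9 libraries, genes called numbered 66 (52 of them shared), 0, 31 (14 shared) and 32 in the joint test, and lists 6, 7 and 9. By the bound set for pairing, the numbers pair WT with hetL1002P libraries but not with those of hetX753, which may rest largely on WT 3 and hetL1002P 3. This block may thus also remove differences that hetX753 does not share. Bub1b had too few counts for the filter of at least 1 CPM, and with only 2 genotypes the joint test gives no value. Sex as a covariate was not run because all libraries had a male pattern. At these depths Bub1b rests on 2 to 21 counts per library, which limits the precision of its fold change.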

Other observations

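The test of chromosome-wide expression here had its prediction written first, and the genes singled out were taken from lists fixed in advance. Of 30 secreted senescence-associated factors, 13 had enough counts to be tested, and 0 passed over all genes in hetX753 against WT (edgeR). Adjusted over the list alone, 4 were lower: the proteinase genes Mmp2 (log2 -0.52), Mmp3 (log2 -1.78) and Mmp9 (log2 -1.41) and the chemokine gene Ccl8 (log2 -2.92). Values adjusted over a list alone, here and elsewhere, were not adjusted over the lists. In hetX753 against WT, 20.9% of all tested genes had an unadjusted p under 0.05 (edgeR), so such calls are weak evidence. The list's median was -0.18 (camera adjusted p = 0.126), and fry's test for change in either direction gave an adjusted p of 0.0131. Mmp3 and Ccl8 were scarce, at 0.196 ± 0.113 and 0.303 ± 0.175 CPM in hetX753, and Ccl8 varied in WT (2.38 ± 2.63 CPM). In hetL1002P 0 of the 13 passed, with a median of -0.05 (camera adjusted p = 0.809), and between the alleles 0 passed (median -0.24, camera adjusted p = 0.0763). In the stress response list, adjusted over the list alone, the chaperone gene Hspa5 (log2 0.39) and the asparagine synthetase gene Asns (log2 0.95) were higher and Aldh18a1 (log2 -1.08) lower in hetX753 (median -0.06, camera adjusted p = 0.681), and Asns was also higher than in hetL1002P (log2 1.27). The circadian list had 3 genes higher and 2 lower in hetX753 adjusted over the list alone, with Tef at 0.40, Per3 at 0.95, Npas2 at -2.99 and Nr1d1 at -0.80 (median 0.32, camera adjusted p = 0.201).

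Apart from fibroblast and macrophage markers, whose calls were lost with an estimated correlation (adjusted p = 0.921 for each), no list of fibre or cell markers passed in hetX753 against WT. Slow-fibre genes had a median of -0.03 but a mean of 0.10 (camera adjusted p = 0.68) and fast-fibre genes a median of -0.18 (0.126), with Csrp3 at 1.38 and Pvalb at -0.58. Smooth muscle and pericyte markers had 13 of 14 members above 0, median 0.30 (0.0747), with Cnn1 at 1.16, and neutrophil and mast cell markers 7 of 7 below 0, median -0.71 (0.0693), with Mcpt4 at -0.95. Tendon markers had a median of -0.32 (0.102), with Scx lower over the list alone (log2 -0.75), heat shock chaperones -0.26 (0.0689), with Hspb7 higher over the list alone (log2 0.99), collagens and matrix -0.15 (0.126), and glycolysis -0.13 (0.203). Immediate early genes had a median of -0.10 (0.528), with Fos at -2.86, glucocorticoid-responsive genes 0.07 (0.533), with Klf9 at 0.77, and interferon genes 0.07 (0.681). Endothelial markers had a median of 0.05 (0.681), atrophy and denervation genes 0.03 (0.681), with Fbxo32 at -0.72, and Schwann cell markers 0.01 (0.681). Adipocyte markers had a median of 0.06 but a mean of -0.14 (0.69), with Adrb3 at -1.81. The values in parentheses are camera adjusted p with the preset correlation. In 3 lists fewer than 5 genes could be tested: lymphocyte markers had 4, with Cd3e (log2 2.80) and Cd28 (log2 0.84) higher over the list alone, erythroid markers had 2, with Alas2 at 0.08, and sex-linked genes had 4, with Ddx3y (log2 0.92), Uty (log2 0.98) and Kdm5d (log2 0.61) higher over the list alone.

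Because the altered gene guards chromosome segregation, a gain or loss of a whole chromosome in most nuclei of a library was tested as a hypothesis. Over 180 combinations of 20 chromosomes and 9 libraries, the median log2 deviation of a chromosome's genes from the other libraries was at most 0.116 in size, at -0.12 for chromosome X in WT 3. Each library was compared with the mean of the others. If expression follows copy number, a gain of a paired chromosome in a single library would give 0.58 in all nuclei. In 46.2% of nuclei it would give 0.3, the bound set beforehand. A loss in as many nuclei, or a change of the single X of male cells, would give a larger deviation. Changes of that extent confined to a single library are argued against for these 20 chromosomes in all 9 libraries. A change shared by several libraries, as within a genotype, would give a smaller deviation and could lie under the bound. One shared by all libraries would give none. Gains in fewer nuclei, or different ones from nucleus to nucleus, would not show in these medians. Y was not among the 20 chromosomes. The 4 sex-linked genes tested had a median log2 fold change of 0.76 in hetX753 against WT, with 0 called over all genes, and the cause was not tested.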
